A study of Mus musculus with 7 samples.

How the data were processed

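Single-cell V(D)J libraries for B cell receptors were prepared from lymph node cells with a Chromium 5' single-cell kit, per the labels' protocols. Cells were labelled with hashtag antibodies (001 to 004), required a viability above 87% and were combined into composite samples, per the labels' protocols. Cell Ranger 6.0.1, Seurat 4.1.0 and the build mm10 are named without a role, per the submitters' processing notes. The deposited tables list 1 assembled contig per line with calls of germline V, D and J segments, per the file headers. The germline set and its version are not given in the sources used here.

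UMI and read numbers per contig are counts as the authors deposited them, per the file headers. The V identity is a fraction from 0 to 1 that the authors deposited, per the file headers. Junction and N region lengths are in bases, per the file headers. All contigs in the tables were marked productive, and none belonged to a T cell receptor locus. The tables hold 40825 contigs of 20052 barcodes over the 6 libraries of a known node and genotype.

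From these tables, cells with exactly 1 productive heavy chain were kept (17381 cells), and isotype shares used the 17178 of them with a constant region call. Barcodes with more than 1 heavy chain, between 2.59% and 5.62% of barcodes with a heavy chain, were left out as possible doublets, and no doublet caller was run because gene expression was not used here. Barcodes with light chains alone were 6.57% to 13% of a library. Cells with IgM or IgD were called unswitched and cells with IgG, IgA or IgE switched. V mutation was the percent of V bases that differed between the aligned sequence and the germline, with gaps and ambiguous bases left out. Between 1 and 4 contigs per library had no germline alignment and gave no mutation value. V calls that named several near-identical genes, 2.56% to 3.17% of cells, were kept as joint names in gene usage and stood under the first name in clones.

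Clones shared the V gene, J gene and junction length and were joined by single linkage at a Hamming distance of at most 0.15 of the junction. The same light chain, where required for clones, meant the same light chain V gene, J gene and junction length. Its sequence was not compared. Clone shares were averaged over 1000 random draws of 2107 cells per library. Shares have exact Clopper-Pearson 95% intervals, and a count of 0 was given the limit of 3 counts. Cells of 1 clone are not independent, so intervals and limits cover counting error only. Intervals of differences combined both exact intervals by square-and-add, those of weighted IgD differences are normal approximations, and those of shared clones are exact Poisson intervals. With 1 library per node and genotype there was no test within a node. Over nodes, 10 measures were compared with WT and 5xFAD libraries paired by node, by an exact two-sided test over the 8 sign patterns of the 3 differences with Benjamini-Hochberg adjustment, added after seeing the data. That test cannot give a p below 0.25, and its pairs are not independent if nodes share animals, which the labels do not give. Clones with identical heavy chain junctions and the same light chain were shared 11 times within genotypes and 2 times across, 1 of these between different nodes. A comparison over animals had been planned for the case that a column gave hashtags, and since no such column was used here it was not run. The library of all nodes and both genotypes was left out of every comparison of nodes or genotypes because its cells could not be assigned to a node or genotype, and its shares were set beside those of the 6 libraries as values.

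The named genes followed a rule written before the data were examined. It took all isotypes and IGHV families. Among IGHV genes at 1% or more of cells in a library it took the 4 largest positive and 4 largest negative differences per node, the 5 largest mean differences each way among genes of one sign in 3 nodes, and the 5 most used. It further took 2 positive and 2 negative differences per node among light chain V genes, lists fixed in advance, and the 3 largest clones per library. Ties between clones were taken in gene order, which the rule had not set. The rule gave 23 IGHV and 8 light chain genes. Coordinates are from GENCODE M21 on GRCm38, the assembly also called mm10, in which 43 of 44 gene names looked up were found, all but IGHG2A.

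Alternatives varied the cell filters, the mutation measure, the clone distance, the thinning and the UMI threshold, 1 choice at a time, except that shared clones with identical junctions and the same light chain changed the distance and the light chain requirement together. Tested on simulated data, the mutation counter was wrong in 0 of 500 sequences, and all of 200 planted clones were recovered in each library. The simulated junctions were random, so that test says nothing of naive cells with similar junctions. Exact intervals held a simulated share in 94.4% to 96.2% of 2000 draws per library. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.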

Results

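B cell receptor repertoires were measured in single cells from deep cervical lymph nodes (dCLN), superficial cervical lymph nodes (sCLN) and inguinal lymph nodes (iLN) of wild-type (WT) and 5xFAD mice. 5xFAD mice are a transgenic model of Alzheimer's disease that develops amyloid deposits in the brain. Cervical nodes receive lymph from the head and the borders of the brain, whereas inguinal nodes drain the flank and hind limb. The animals were females aged 10 to 11 months. Each of the 6 combinations of node and genotype was represented by 1 library, so no difference within a node has a replicate check, and there the libraries, not the genotypes, were compared. Intervals are exact Clopper-Pearson 95% intervals that cover counting error only, and a difference was taken as larger than counting error where the intervals of both libraries did not overlap. That rule is stricter than asking whether the interval of the difference is all of one sign. Some differences below have such an interval although the intervals of the libraries overlapped. A library that mixed all nodes and both genotypes entered no comparison of nodes or genotypes. Over the 3 nodes, genotypes were also compared with libraries paired by node in an exact two-sided sign-flip test, added after seeing the data, whose smallest possible p is 0.25, so it could not reach a threshold of 0.05. Of 10 measures, 7 had one sign in all nodes and this p (exact test, Benjamini-Hochberg adjusted p = 0.357, n = 3 nodes), the switched and IgA shares had an exact p of 0.5, and the share of cells in clones an exact p of 1.

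The 6 libraries held between 2398 cell barcodes (5xFAD iLN) and 4411 (5xFAD dCLN), with 99906 to 312484 immunoglobulin UMIs per library. A single productive heavy chain was present in 3374 cells of the WT dCLN, 3904 of the 5xFAD dCLN, 3440 of the WT sCLN, 2356 of the 5xFAD sCLN, 2200 of the WT iLN and 2107 of the 5xFAD iLN. The median number of heavy chain UMIs per cell ranged from 9 in the WT dCLN to 13 in the 5xFAD dCLN. Reads per UMI ranged from 26 in the WT dCLN to 114 in the WT iLN.

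Class-switched cells (IgG, IgA or IgE) were a small part of every library and were more frequent in the cervical than in the inguinal libraries. In WT mice they made up 4.1% of the dCLN cells (3.45 to 4.84, 136 cells), 4.23% of the sCLN cells (3.58 to 4.96, 144 cells) and 1.43% of the iLN cells (0.974 to 2.02, 31 cells). In 5xFAD mice the shares were 4.11% in the dCLN (3.51 to 4.79, 159 cells), 2.90% in the sCLN (2.26 to 3.66, 68 cells) and 1.20% in the iLN (0.778 to 1.77, 25 cells). The cervical and inguinal intervals were apart in both genotypes, with ratios to the iLN of 2.87 and 2.96 for the WT dCLN and sCLN, and of 3.43 and 2.42 for the 5xFAD dCLN and sCLN. IgG followed the same order, at 3.59% of WT dCLN cells and 3.54% of 5xFAD dCLN cells against 1.25% and 1.10% in the iLN, with intervals apart. IgA was rare, with its highest share of 0.569% (0.357 to 0.860) in the 5xFAD dCLN.

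**Figure D1:**
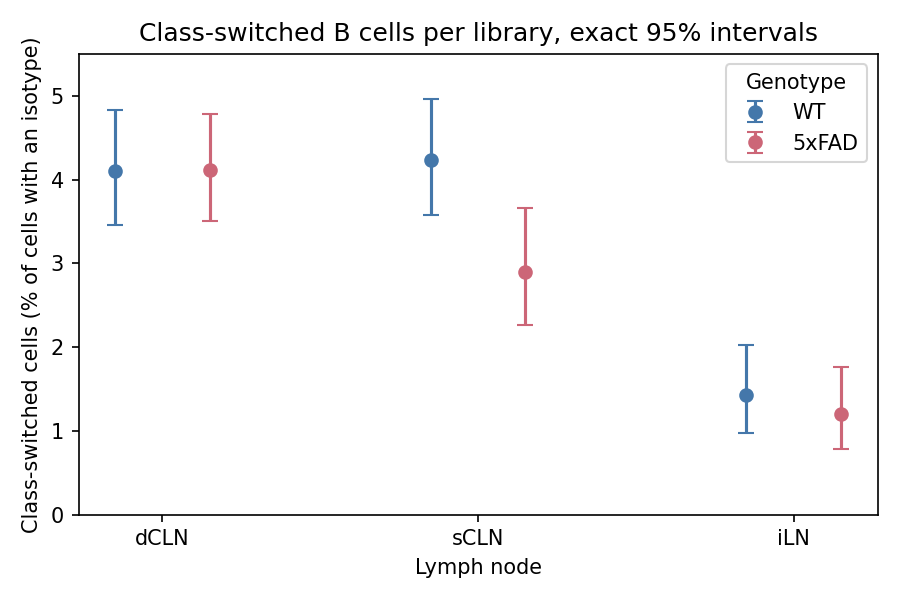
Share of class-switched cells (vertical axis, percent of cells with 1 productive heavy chain and an isotype) in each node (horizontal axis) for WT and 5xFAD libraries, with exact 95% intervals as bars. The cervical libraries lie between 2.90% and 4.23%, and the inguinal libraries at 1.20% and 1.43%.

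The library mixing all nodes and both genotypes had a switched share of 6.93% (5.95 to 8.01), above those of all 6 libraries with intervals apart. If it was prepared like them, switched shares varied between libraries by more than counting error. The cervical and inguinal intervals do not cover such variation. Between genotypes, the intervals of the switched share overlapped in each node. The difference, 5xFAD minus WT, was 0.00898 percentage points in the dCLN (-0.940 to 0.946), -1.33 in the sCLN (-2.30 to -0.325) and -0.231 in the iLN (-0.959 to 0.496). In the sCLN the call depended on the filter: among cells with at least 3 heavy chain UMIs the shares were 4.17% in WT (3.51 to 4.91) and 2.47% in 5xFAD (1.87 to 3.19), and among cells with a light chain 4.20% (3.55 to 4.93) and 2.76% (2.13 to 3.50), with intervals apart in both.

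The make-up of the switched cells differed between the WT and 5xFAD dCLN libraries. IgG2c, encoded by IGHG2C (GRCm38 chromosome 12, 113285325 to 113288932) and characteristic of type 1 and antiviral responses in C57BL/6 mice, was the isotype of 40.4% of switched WT dCLN cells (32.1 to 49.2, 55 cells) and 22.6% of switched 5xFAD dCLN cells (16.4 to 29.9, 36 cells). IgG1, encoded by IGHG1 (chromosome 12, 113325240 to 113330523) and associated with T helper type 2 responses, made up 9.56% (5.19 to 15.8) and 20.1% (14.2 to 27.2), with overlapping intervals. IgG2b made up 35.3% and 38.4%, IgA 12.5% and 13.8%, and IgG3 2.21% and 5.03%. The IgG2c shares were 34.0% in WT and 30.9% in 5xFAD in the sCLN, and 16.1% and 12% in the iLN, with overlapping intervals. Within WT mice, the IgG1 share of the dCLN lay below those of the sCLN (23.6%) and iLN (35.5%), with intervals apart. Within 5xFAD mice the IgG1 shares were 20.1% in the dCLN, 27.9% in the sCLN and 28% in the iLN, with overlapping intervals. The IgG2c call in the dCLN ended when repeated cells were counted once: with each clone counted once the shares were 41.7% (31.7 to 52.2) and 24.6% (17.4 to 33.1), and with identical barcodes counted as 1 cell 40% (31.0 to 49.6) and 23.4% (16.8 to 31.2), with overlapping intervals in both. The difference stayed about as large. It was -17.8 percentage points with all cells, and -17.1 and -16.6 in these 2 settings. As a share of all cells with an isotype, IgG2c was at 1.66% (1.25 to 2.15) and 0.931% (0.653 to 1.29), also overlapping. No cell was called IgG2a, the allelic form of other strains, or IgE. For IgE this allows up to 0.0905% of WT dCLN cells and up to 0.144% of 5xFAD iLN cells. The name IGHG2A was not found in the annotation used for coordinates, and the reference behind the calls is not given. The absence of IgG2a calls may therefore say nothing.

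Contigs called IgM were more frequent and contigs called IgD less frequent in 5xFAD than in WT cervical libraries. Of all cells with an isotype, IgM made up 69.2% in the WT dCLN (67.6 to 70.7) and 80.1% in the 5xFAD dCLN (78.8 to 81.4), and 73.3% (71.7 to 74.7) and 78.3% (76.5 to 79.9) in the sCLN. IgD made up 26.7% and 15.8% of the cells in the dCLN, 22.5% and 18.8% in the sCLN, and 21.5% and 20.3% in the iLN, where the intervals overlapped. IGHM and IGHD (chromosome 12, 113418558 to 113422730 and 113406604 to 113416324) are expressed together by alternative splicing in naive B cells, and each contig carries 1 constant region call. The call depended on depth: in the WT dCLN it was IgD in 55.3% of unswitched cells with 1 or 2 heavy chain UMIs and in 6.33% of those with 21 or more. With both genotypes weighted to the same distribution of UMIs, a step chosen after seeing the data, the IgD difference among unswitched cells was -5.22 percentage points in the dCLN (-7.14 to -3.30). It was -1.51 in the sCLN (-3.54 to 0.528), where the interval of the difference held both signs. The weights used bins of UMIs, within which depth can still differ.

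V regions of switched cells carried mutations and those of unswitched cells almost none. Mean V mutation of switched cells was 2.87% in WT and 2.22% in 5xFAD dCLN (SD over cells 2.55 and 2.02), 2.87% and 2.70% in the sCLN (SD 2.81 and 2.76), and 2.70% and 2.19% in the iLN (SD 2.13 and 2.24). The difference, 5xFAD minus WT, was -0.652 percentage points in the dCLN, -0.176 in the sCLN and -0.511 in the iLN, with a mean over nodes of -0.446 ± 0.244 (SD, n = 3, exact sign-flip p = 0.25). The sCLN difference ranged from -0.0662 with at least 3 heavy chain UMIs to -0.281 with each clone counted once, and the iLN difference was -0.314 with each clone counted once. The share of switched cells with at least 1% mutation was 70.6% (62.2 to 78.1) and 63.5% (55.5 to 71.0) in the dCLN, 69.4% and 73.5% in the sCLN, and 80.6% and 64% in the iLN, with overlapping intervals throughout. Unswitched cells had means from 0.0153% to 0.0292%, taken as the background of the measure.

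Cells in clones of 2 or more were more frequent in the WT dCLN than in the other libraries when each barcode was counted. At 2107 cells per library they made up 13% of WT and 6.89% of 5xFAD dCLN cells, 9.74% and 10.8% of sCLN cells, and 8.68% and 9.68% of iLN cells. Shares were lower when the same light chain was also required, a setting chosen after seeing the data. They were then 9.49% and 3.31% in the dCLN, 6.42% and 6.82% in the sCLN, and 5.31% and 6.98% in the iLN. Without thinning, 17.5% of unswitched WT dCLN cells (16.2 to 18.9) and 10.4% of unswitched 5xFAD dCLN cells (9.40 to 11.4) were in clones. Among switched cells the shares were 42.6% (34.2 to 51.4) and 28.9% (22.0 to 36.6) in the dCLN, 20.1% and 16.2% in the sCLN, and 12.9% (4 of 31 cells) and 0 of 25 cells in the iLN, which allows up to 12%, with overlapping intervals in each node. The dCLN difference of -6.09 percentage points was -0.476 when barcodes with an identical heavy chain and an identical light chain junction were counted as 1 cell, a choice made after seeing the data, and -3.23 at 1053 cells per library. The sCLN difference of 1.09 was -3.04 without thinning, and the iLN difference of 1.00 was -0.802 with identical barcodes counted as 1 cell.

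**Figure D2:**
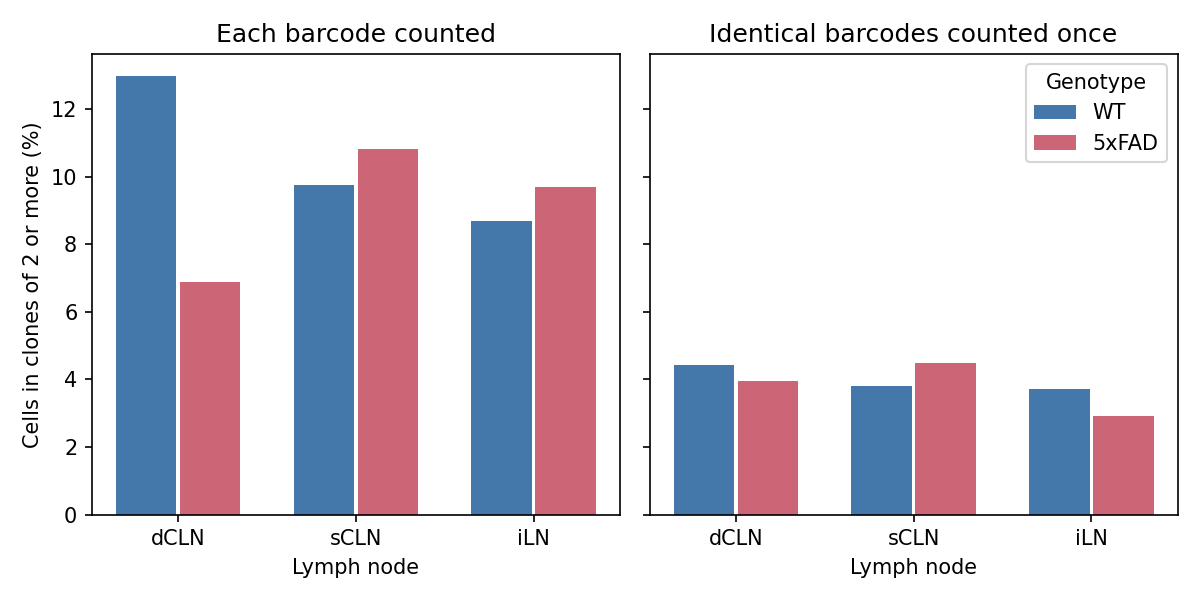
Share of cells in clones of 2 or more (vertical axis, percent, mean over 1000 random draws) by node (horizontal axis) and genotype, with each barcode counted (left, 2107 cells per library) and with barcodes of identical heavy and light chains counted once (right, 2032 cells per library). The WT dCLN bar stands at 13% on the left and 4.42% on the right, and the 5xFAD dCLN bar at 6.89% and 3.94%.

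The largest clone of each dCLN library held switched, mutated cells. In the 5xFAD dCLN, a clone of 8 cells used IGHV1-82 and IGHJ4 with IGKV4-57, with 7 IgG1 cells and 1 IgM cell, 8 different heavy chain junctions and 1.02% to 3.06% mutation. It was followed by clones of 6 cells using IGHV1-53 with IGHJ2 (4 IgG2b and 2 IgM cells) and IGHV3-3 with IGHJ1 (3 IgG1, 2 IgM and 1 IgG3 cells). In the WT dCLN, a clone of 6 cells used IGHV1-26 and IGHJ2, with 2 cells each of IgG2c, IgG2b and IgG1 and a mean mutation of 4.25%, followed by 5 unswitched cells of IGHV1-26 with IGHJ4 and 5 unswitched cells of IGHV1-81 with IGHJ4. The largest clone of the WT sCLN held 9 unmutated IgM cells of IGHV1-26 with IGHJ4 and IGKV2-137, followed by IGHV1-22 with IGHJ3 (5 cells) and IGHV1-52 with IGHJ2 (4 cells). In the 5xFAD sCLN the largest were IGHV3-6 with IGHJ1 (4 cells), IGHV1-18 with IGHJ4 and IGHV1-26 with IGHJ2 (3 cells each). Inguinal clones had at most 3 cells, and those named first by gene order used IGHV1-18, IGHV1-74 and IGHV1-81 in WT and IGHV1-15, IGHV1-26 and IGHV1-52 in 5xFAD, all IgM or IgD where an isotype was called. Heavy chain similarity joined cells of different light chains in some of these groups: the commonest light chain was in 2 of 5 cells of the IGHV1-22 group and in 1 of 4 cells of the IGHV3-6 group. Other groups held 1 distinct heavy chain junction and the commonest light chain in every cell. Among them were the 9 WT sCLN cells of IGHV1-26 and the 5 WT dCLN cells of IGHV1-81. Whether such barcodes are sister cells or RNA of 1 cell was not decided.

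Clones joined by heavy chain similarity were shared between libraries at overlapping rates within and across genotypes, and pairs of different genotype cannot share an animal. Counting each clone once per pair of libraries, 15.3 clones per 1000000 pairs of cells were shared between nodes of the same genotype (14.3 to 16.5, Poisson interval) and 14.7 between libraries of different genotype (13.9 to 15.6). With identical junctions the rates were 0.265 (0.141 to 0.454, 13 occurrences) and 0.133 (0.0636 to 0.244, 10 occurrences). A further step, chosen after seeing the data, also required the same light chain V gene, J gene and junction length. Light chain sequences were not compared, so these need not be identical receptors. Then 11 occurrences within and 2 across genotypes remained, at 0.225 (0.112 to 0.402) and 0.0265 (0.00321 to 0.0958), with intervals apart. Pairs of the same genotype are always of different nodes, and over the 6 pairs of different genotype and different node 1 occurrence gave 0.0202 (5.11e-04 to 0.113), where the intervals overlapped. These intervals treat occurrences as independent, although 1 clone of IGHV1-26 supplied 3 of the 11 and 1 clone of IGHV4-1 both of those across genotypes. With each clone counted once, 9 clones were shared within genotypes (0.184, 0.0840 to 0.349) and 1 across (0.0133, 3.4e-04 to 0.0739), with intervals apart over all pairs and overlapping when those across genotypes were limited to different nodes. The 5xFAD pairs alone had 3 occurrences (0.134, 0.0276 to 0.392), with an interval overlapping that across genotypes, and the WT pairs 8 (0.301, 0.130 to 0.593), with an interval apart from it, also over different nodes alone. The IGHV1-26 clone supplied 3 of these 8, and the WT rate was not computed with each clone counted once, so that call may not hold. The IGHV1-26 and IGHJ4 clone with IGKV2-137 was in all 3 WT nodes (4 cells in dCLN, 9 in sCLN, 2 in iLN) and was not seen in a 5xFAD library. An IgG2b clone of IGHV1-76, IGHJ1 and IGKV10-96 without V mutations was in the WT dCLN (3 cells) and sCLN (2 cells), with a median of 408 heavy chain UMIs per cell, and an IgA clone of IGHV1-64, IGHJ4 and IGKV3-2 was in the same nodes with 1 cell each and a median of 1548 UMIs. These shared clones were chosen after their values were seen.

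High-immunoglobulin cells, with at least 100 heavy chain UMIs and used as a proxy for antibody-secreting cells, were rare in every library. They numbered 21 in WT dCLN (0.634%, 0.393 to 0.967), 16 in 5xFAD dCLN (0.414%, 0.237 to 0.671), 23 in WT sCLN (0.676%, 0.429 to 1.01), 4 in 5xFAD sCLN (0.171%, 0.0465 to 0.437), 3 in WT iLN (0.138%) and 1 in 5xFAD iLN (0.0480%). In WT mice the sCLN share was 4.88 times that of the iLN, with intervals apart. The WT dCLN, 5xFAD dCLN and 5xFAD sCLN shares were 4.58, 8.62 and 3.56 times those of the iLN, with overlapping intervals. Between genotypes the intervals overlapped in each node, with differences of -0.220 percentage points in the dCLN (-0.597 to 0.133), -0.505 in the sCLN (-0.864 to -0.142) and -0.0905 in the iLN (-0.360 to 0.155). The 21 WT dCLN cells came from 13 clones, and with identical barcodes counted as 1 cell the dCLN difference was -0.0563 (-0.410 to 0.274). IgG2b, IgG2c and IgM contributed 7, 6 and 6 of the 21 cells in the WT dCLN, from 5, 3 and 3 clones, and IgM, IgA and IgG2c 8, 5 and 5 of the 23 in the WT sCLN. In the 5xFAD dCLN 9 of the 16 were IgA, or 40.9% of its IgA cells (20.7 to 63.6) against 11.8% (1.46 to 36.4) in WT, with overlapping intervals. In the 5xFAD sCLN 0 of 68 switched cells passed the threshold, which allows up to 4.41%, against 15 of 144 (10.4%) in WT, with intervals apart, while the dCLN and iLN intervals overlapped. Of the heavy chain UMIs of cells with an isotype, high cells held 57.9% in the WT and 26.3% in the 5xFAD dCLN, 56.7% and 3.51% in the sCLN, and 1.24% and 1.65% in the iLN. In the 5xFAD dCLN a single cell held 11129 of the 19212 UMIs of the high cells. The threshold mattered. At 50 UMIs the differences were 0.0863 in the dCLN, -0.511 in the sCLN (-1.06 to 0.0648) and -0.495 in the iLN, with overlapping intervals of the libraries. At 10 times the median of unswitched cells they were -0.276, -0.518 and 0.00184, and the sCLN shares were 0.646% (0.405 to 0.977) in WT and 0.128% (0.0264 to 0.374) in 5xFAD, with intervals apart.

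Heavy chain V gene usage was alike in the 6 libraries. The family IGHV1 was used by 56.7% to 59.1% of cells, and the D-proximal families IGHV2 and IGHV5 together by 16% and 15% in WT and 5xFAD dCLN, 16.7% and 14.8% in the sCLN, and 16.5% and 15.2% in the iLN, with overlapping intervals in each node. Intervals of WT and 5xFAD overlapped in every node for each IGHV family and each IGHJ gene. The Jensen-Shannon distances between genotypes, 0.110 in the dCLN, 0.124 in the sCLN and 0.141 in the iLN, lay inside the ranges that random draws from the pooled usage gave. Of 44 genes used by at least 1% of cells in a library, 11 differed in one direction in all 3 nodes, and 11 would do so by chance if the nodes were independent. Without the dCLN libraries 20 shared a sign, against 22 by chance on the same assumption. The labels do not say whether nodes of one genotype came from the same animals, and shared animals would raise these chance counts. Clones with identical heavy chain junctions and the same light chain were shared 11 times within genotypes and 2 times across, 1 of these between different nodes.

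Single IGHV genes differed by at most 1.40 percentage points between genotypes, the largest being IGHV9-3 in the sCLN (3.23% in WT, 4.63% in 5xFAD), where the intervals overlapped in all cells and were apart in unswitched cells alone (3.19%, 2.61 to 3.85, and 4.79%, 3.95 to 5.75). IGHV14-3 (chromosome 12, 114059845 to 114060321) was at 0.889% (0.601 to 1.27) in WT and 1.66% (1.29 to 2.12) in 5xFAD dCLN, with intervals apart. This call ended in unswitched cells alone (0.913%, 0.612 to 1.31, and 1.67%, 1.28 to 2.14), with a light chain required (0.904% and 1.66%), with at least 3 heavy chain UMIs (0.878% and 1.58%) and with each clone counted once (0.992% and 1.75%), while the difference stayed about as large. IGHV14-3 was at 1.28% and 1.91% in the sCLN and at 1.09% and 1.28% in the iLN, with overlapping intervals. IGHV1-76 (chromosome 12, 115847881 to 115848331) was lower in the 5xFAD sCLN, at 1.95% (1.51 to 2.47) in WT and 0.891% (0.553 to 1.36) in 5xFAD, with intervals apart, and stood at 1.54% and 1.33% in the dCLN and 1.23% and 1.33% in the iLN. IGHV1-42, IGHV1-50, IGHV1-55 and IGHV1-72 had positive differences in all 3 nodes, of 0.0323 to 0.632 percentage points, with overlapping intervals. IGHV2-2 (chromosome 12, 113588267 to 113588702) was at 3.23% and 2.33% in the dCLN, 3.55% and 2.84% in the sCLN, and 2.86% and 2.28% in the iLN, with overlapping intervals. IGHV5-17, IGHV14-4, IGHV1-75 and IGHV1-74 also had negative differences in all nodes, with overlapping intervals. The other genes with the largest differences in a node had overlapping intervals as well. In the dCLN, IGHV1-26 was at 5.54% in WT and 6.38% in 5xFAD, IGHV1-80 at 2.13% and 2.89%, and the pair IGHV1-62-2/IGHV1-71, which the calls could not separate, at 1.16% and 0.666%. In the sCLN, IGHV14-2 was at 1.28% and 1.95% and IGHV1-18 at 1.80% and 2.42%. In the iLN, IGHV8-12 was at 1.45% and 2.42%, IGHV6-3 at 1.09% and 1.71%, and IGHV2-5 at 1.23% and 0.617%. The most used genes were IGHV1-26, IGHV9-3, IGHV3-6, IGHV8-8 and IGHV1-64.

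The V genes listed in advance for known specificities showed no genotype difference beyond counting error. IGHV11-2 (chromosome 12, 114048241 to 114048812) and IGHV12-3, typical of phosphatidylcholine-binding B-1a cells, were found in 0 to 4 and 1 to 2 cells per library. IGHV7-1, used in the phosphorylcholine response, was found in 0.179% to 0.382% of cells, and IGHV1-72, used in the nitrophenyl response of C57BL/6 mice, in 2.33% to 2.82%.

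Light chains were mostly kappa. Lambda was used by 4.27% and 4.01% of cells with 1 light chain in WT and 5xFAD dCLN, 5.02% and 4.22% in the sCLN, and 4.66% and 4.45% in the iLN, with overlapping intervals. IGKV1-135 (chromosome 6, 67609713 to 67610508) was lower in the 5xFAD iLN, at 3.91% (3.15 to 4.79) in WT and 2.25% (1.67 to 2.96), with intervals apart, and stood at 3.57% and 2.59% in the dCLN and 2.93% and 2.13% in the sCLN, with overlapping intervals. IGKV6-20 (chromosome 6, 70335841 to 70336507) was lower in the 5xFAD dCLN, at 1.56% (1.18 to 2.03) in WT and 0.621% (0.398 to 0.922), and higher in the 5xFAD iLN, at 0.311% (0.125 to 0.640) in WT and 1.33% (0.893 to 1.91). The WT and 5xFAD cells of this gene held 13 and 7 distinct junctions in the dCLN and 3 and 7 in the iLN. Light chain shares were not computed with each clone counted once. IGKV9-120 had differences of -0.448, -0.759 and -0.623 percentage points in the dCLN, sCLN and iLN, and IGKV6-15 was at 3.41% and 4.47% in the sCLN and 3.73% and 2.66% in the iLN, all with overlapping intervals. IGKV6-32 in the dCLN had overlapping intervals in cells with 1 light chain and intervals apart, at 1.80% (1.41 to 2.26) and 2.77% (2.30 to 3.30), when the light chain of most UMIs was taken in every cell, a setting added after seeing the data. IGKV6-23, IGKV12-41 and IGKV4-59, named for their difference in a single node, had overlapping intervals. Of 48 light chain genes at 1% or more in a library, 16 differed in one direction in all nodes, against 12 by chance if the nodes were independent, which the labels do not say. IGHJ2 was the most used J gene of the heavy chain, in 33.0% to 34.1% of cells.

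Heavy chain CDR3s of unswitched cells averaged 12.1 amino acids in the WT dCLN (SD over cells 2.69) and 12.1 in the 5xFAD dCLN (SD 2.63), with differences between genotypes of at most 0.0756 amino acids in any node. The share of unswitched heavy chains without N additions, a feature of B cells made early in life, was 1.13% (0.795 to 1.56) and 1.73% (1.33 to 2.20) in the dCLN, 1.44% and 1.23% in the sCLN, and 2.06% (1.5 to 2.76) and 1.26% (0.826 to 1.84) in the iLN, with overlapping intervals.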

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

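All patterns weighed here and all tests of them were chosen only after the pattern was seen, as were the measures of the mixed library and the limiting of opposite directions to intervals that were apart. The bounds for the tests of the IgD calls by merged barcodes and by reads, and for both tests of IgG2c, were written before those tests were computed, and the others after.

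The library that mixes all nodes and both genotypes is listed because it enters no comparison of nodes or genotypes. Switched cells made up 6.93% of its cells (5.95 to 8.01), with an interval apart from that of the highest of the 6 libraries, the WT sCLN at 4.23% (3.58 to 4.96). A mix of the same nodes lies inside the range of its parts, so if it was prepared like them, switched shares varied between libraries by more than counting error. Shares of the mixed library were not computed with each clone or identical barcode counted once. IgG2c made up 51.5% of its switched cells (43.7 to 59.2), against at most 40.4% (32.1 to 49.2) in the WT dCLN, and cells with at least 100 heavy chain UMIs 1.23% (0.831 to 1.75), against at most 0.676% (0.429 to 1.01) in the WT sCLN, both with overlapping intervals. Barcodes with more than 1 heavy chain, left out of the comparisons, made up 5.62% of heavy chain barcodes in the WT dCLN, 5.27% in the 5xFAD dCLN, 3.64% in the WT sCLN, 3.99% in the 5xFAD sCLN, 2.78% in the WT iLN and 2.59% in the 5xFAD iLN. The light chain gene IGKV6-20 had opposite genotype differences in the dCLN and iLN, of -0.943 and 1.02 percentage points, and the difference between nodes was not tested. Its cells held fewer distinct junctions than cells, and junctions of other light chain genes were not counted for comparison. There were 13 in 56 WT and 7 in 24 5xFAD dCLN cells, and 3 in 7 WT and 7 in 29 5xFAD iLN cells. Cells of 1 junction may or may not be of 1 clone, and light chain shares were not computed with each clone or identical barcode counted once.

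Cells in clones of 2 or more were more frequent in the WT than in the 5xFAD dCLN. Expansion of switched or mutated cells as the whole cause is argued against by a difference of -5.94 percentage points (-7.78 to -4.15) among unswitched cells with 0 mutations. Barcode pairs with identical heavy and light junctions were counted among unswitched cells with 0 mutations alone. Of 229 such pairs in the WT library, 0 differed at 2 bases or fewer, which allows up to 1.31%. For these cells that argues against sequencing errors in cell barcodes. RNA of 1 cell under 2 barcodes and true sister cells cannot be told apart by these values. In the WT dCLN the median of heavy chain UMIs in paired barcodes was 0.7 times that of unpaired ones (0.6 to 0.7). That lies between the values of a split and a whole cell. The ratio was below 1 in all 6 libraries, from 0.583 in the 5xFAD iLN to 0.833 in the 5xFAD sCLN and WT iLN. Of 200 barcodes with exactly 2 heavy chains, both heavy chains of 12 recurred together in another barcode. In 30 a heavy chain recurred but not both together, and in 158 none did. A difference in clonal expansion between genotypes stays open, since the test paired by node could not reach a threshold of 0.05 and gave a mean difference of -1.33 percentage points (SD 4.12, n = 3 nodes, exact p = 1) from -6.09, 1.09 and 1.00 in the dCLN, sCLN and iLN. With identical barcodes counted as 1 cell, which removes such pairs by construction, the dCLN shares were 4.42% in WT and 3.94% in 5xFAD.

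IgD calls were more frequent in the WT than in the 5xFAD dCLN. UMI depth may account for part, since the difference weighted over UMI bins was -5.22 percentage points (-7.14 to -3.30), against -11.5 unweighted. Depth as the whole cause is argued against only between bins, as depth can differ within a bin. The UMIs are also those of the called contig, with medians of 7 for IgD and 10 for IgM in the WT dCLN. IgD shares in WT and 5xFAD were 47.1% and 53.6% at 3 to 4 UMIs and 39.3% and 38.0% at 5 to 6. At 14 to 20 they were 16.7% and 8.30%, with intervals apart. Repeated barcodes of 1 cell are argued against by a difference of -11.3 (-13.3 to -9.27) with such barcodes counted once. Reads per heavy chain as the whole cause are argued against by a difference of -11.8 (-13.9 to -9.61) at equal reads. A genotype difference stays open, since the test paired by node gave -5.29 percentage points (SD 5.08, n = 3 nodes, exact p = 0.25, adjusted p = 0.357), the lowest p it can give, and a property of these libraries was not tested.

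IgG2c was a larger part of switched cells in the WT than in the 5xFAD dCLN, a pattern picked from 7 isotypes in 3 nodes. Shallow cells with uncertain calls are argued against by a difference of -19.3 percentage points (-32.0 to -6.17) among cells with at least 5 heavy chain UMIs. With each clone counted once the difference was -17.1 (-29.8 to -3.98), about as large as the -17.8 with all cells. A few expanded clones stay open only because the upper end of this wider interval did not pass the bound written before the value was computed. The intervals of the libraries also overlapped. A genotype difference stays open, since the same paired test gave -8.36 percentage points (SD 8.19, n = 3 nodes, exact p = 0.25, adjusted p = 0.357), and responses of single animals were not tested.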

How the results depend on the processing

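No paired analysis by replicate number was possible because the labels give no replicate numbers. Pairing libraries by node, added after seeing the data, gave exact p of 0.25, the smallest it can give, for 7 of 10 measures. Of 207 alternative values of 36 main shares and rates, 196 stayed within the interval of the value as reported, 11 moved outside it, and 11 had another sign or were 0; 0 of the differences beyond counting error changed sign. Mean V mutation and CDR3 length have no interval without replicates, so their alternatives were held to a factor of 1.5, a rule set after seeing the data. Of 81 such values of 12 mean differences, 61 stayed within it, 20 moved by more, and 2 of these changed sign. All 414 alternative values of 69 named IGHV results and all 48 of 24 named light chain results stayed within their intervals, 6 and 3 with another sign or 0. Library intervals were compared again for 12 differences with intervals apart. Of their 60 alternative values, 6 had overlapping intervals, all for IgG2c and IGHV14-3 in the dCLN. Of 561 alternative values of overlapping differences 6 came apart. Other calls of intervals apart were not repeated in this way. Among them were IgD shares, IgG and IgG1 shares between nodes, switched cells with high UMIs, and clone shares. Settings that merge identical barcodes, require the same light chain or leave out the dCLN, and those of IgG2c, the cervical minus inguinal share, the gene count and the light chain genes were chosen after seeing the data. The clone share difference in the dCLN was -3.23 percentage points at 1053 cells, where fewer cells leave fewer clones, and -0.476 with identical barcodes counted as 1 cell, which removes such pairs by construction. In the sCLN it was -3.04 without thinning, which leaves the larger WT library more clones, and in the iLN -0.802 with identical barcodes counted as 1 cell. Shared clones per 1000000 cell pairs, within and across genotypes, were 4.51 and 4.12 at a junction distance of 0.10, 0.265 and 0.133 with identical junctions, and 0.225 and 0.0265 with the same light chain also required, each a stricter definition. The share with high UMIs differed by -0.495 percentage points in the iLN at 50 UMIs; the cause was not tested. IGHV genes of one sign numbered 20 without the dCLN libraries, where fewer nodes need to share it, and the other 6 values of that count stayed within 1.5 times. The V mutation difference of switched cells was -0.0991 percentage points in the sCLN with a light chain required, -0.0662 with at least 3 heavy chain UMIs, -0.281 with each clone counted once and -0.269 with identical barcodes counted as 1 cell, and -0.314 in the iLN with each clone counted once. That of unswitched cells was -0.00218 in the sCLN with several heavy chains allowed, -0.00303 by the deposited identity, and -0.00279 in the iLN with at least 3 UMIs. The CDR3 length difference of unswitched dCLN cells was 0.0407 amino acids with several heavy chains allowed, 0.000722 with each clone counted once and -0.00432 with identical barcodes counted as 1 cell. That of switched cells was 0.00999 in the dCLN with several heavy chains allowed and 0.250 with each clone counted once, and -0.106 in the sCLN with a light chain required and -0.325 with at least 3 UMIs. In the iLN it was 0.0459, 0.0533, -0.256, 0.303 and 0.287 with several heavy chains allowed, a light chain required, at least 3 UMIs, each clone counted once and identical barcodes counted as 1 cell. The causes of these moves were not tested. Switched cells numbered 25 to 159 per library, which limits isotype and mutation comparisons most in the iLN.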

Other observations

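The clones and genes described here were chosen after their values were seen. In the mixed library the largest clone held 8 IgG2c cells of IGHV5-17 and IGHJ2 with a mean mutation of 3.78%, followed by 7 IgG2c cells of IGHV1-55 and IGHJ2 with 3.40% and 5 IgM cells of IGHV1-53 and IGHJ3 with 1.84%. The 7 IGHV1-55 barcodes had 1 distinct heavy chain junction, the same V mutation, IGKV3-7 in all 7 and a median of 2 heavy chain UMIs. Whether they are 7 cells or RNA of fewer cells was not tested. Of 6 joint V names in this library, 3 were in none of the other 6 libraries, so its V calls, V usage and mutation values cannot be set beside theirs without knowing that the germline sets were the same. IgG1 made up 2.37% of the switched cells of this library (0.649 to 5.95). Lambda was used by 5.63% of its cells (4.79 to 6.56), and IGHV1 by 53.5% (51.5 to 55.5).

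A clone of IGHV4-1, IGHJ1 and IGKV1-110 with identical heavy chain junctions was in the 5xFAD dCLN (5 cells), the WT dCLN (1 cell) and the WT iLN (1 cell), all IgM, with a mean mutation of 0.338%. A clone of IGHV8-8, IGHJ2 and IGKV6-15 without V mutations, with 2 IgG2c cells and 1 IgG2b cell, was in the 5xFAD dCLN (2 cells) and sCLN (1 cell).

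In each of the 6 libraries, the median V mutation of unswitched IGHV1-69 cells was 0.34% of bases, and that of unswitched IGHV2-6-1/IGHV2-6-2 cells 0.341%, while unswitched cells of all genes together had means of at most 0.0292%.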
